A study of Mus musculus with 9 samples.

How the data were processed

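Bone marrow LSK cells of 4 Abi1 KO and 5 WT mice were profiled on Affymetrix whole-transcript arrays, 1 array per mouse. Per the labels' protocols, lineage-depleted marrow was stained for c-Kit and Sca-1 and sorted, total RNA was purified, and 5 ng per sample was pre-amplified, transcribed, converted to cDNA and labelled with biotin. Recombination was tested by PCR in the marrow, and the replicates are separate mice, per the labels. The labels name no litter, sort day, scan day or other batch.

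The deposited values, 1 table of 72688 probesets by 9 arrays, were used as log2 signals summarised and normalized by the authors. The log base, the background correction and the normalization are not given in the sources used here, and Partek 6.6 is the tool named in the submitters' processing notes. The values run from 1.84 to 19.45 with array medians of target probesets from 5.08 to 5.33, a range that fits a log2 scale. Every fold printed rests on that reading. Values carry 2 decimals, and 7779 genes (25.8%) hold one identical value in at least 5 of the 9 arrays, 5659 of them below background. Equal values in arrays of different mice make the measured spread of these genes small, and 132 genes hold 1 value in all 9 arrays.

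Probesets were named from the array's platform annotation, in which 827 symbols were updated through their Entrez identifiers to the RefSeq annotation of assembly GRCm38.p6. Of the probesets, 6732 were controls by their identifiers: 5222 marked neg, 1324 marked pos, 155 ERCC spike-ins, 23 antigenomic probesets and 8 bacterial and phage spike-ins. The neg and pos probesets were set aside as controls only after the results had been seen, which moves the medians, the quantile normalization and the counts over all probesets, but no gene of the main comparison. Of the other 65956, 30604 carried exactly 1 symbol, 2146 carried several and 33206 were not listed, which leaves them unnamed here. The brightest probeset stood for each of 30142 genes, 355 of which had more than 1 probeset. Genes known only from probesets with several symbols were not tested, and Ly6a, the gene of the Sca-1 gate, had no probeset of its own in the annotation.

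Background was the percentile 95 of 1717 olfactory and vomeronasal receptor genes in each array, at log2 signals of 5.29 to 5.64. By that measure 16023 genes had a mean above background. The number of arrays limits the precision: the median standard error of a log2 difference was 0.13 for genes above background, and 90% of them had one under 0.27.

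KO and WT were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, Benjamini-Hochberg adjustment, threshold 0.05), with no covariate. Single values were also tested with exact two-sided permutation over the 126 splits of 9 arrays into 4 and 5. Before the data were examined, 36 gene lists, the test, the alternatives and the naming rule were fixed. Lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists tested), with camera at an estimated correlation, with fry, and by exact permutation of array scores. An array score is the mean deviation of the list's members from their means over 9 arrays. The list of mitochondrially encoded transcripts had 1 matched gene of 12 and was not tested, since a list needed 5 members, so 35 lists were tested. Matches fell short elsewhere too, with 15 of 22 erythroid genes (no globin gene) and 14 of 28 ribosomal protein genes.

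The naming rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, and filled empty places with the smallest unadjusted p in that direction. It added Abi1, Abi2, Abi3, Kit and Ly6a and, per list, up to 2 members per direction with the smallest p among those under 0.05. Model names, micro- and small nucleolar RNAs and receptor genes were skipped outside the lists. Further list members, among them the other WAVE genes, Mpo, Car1, S100a8 and Jchain, are named as examples chosen after their values were seen.

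On simulated arrays with independent noise, the gene test recovered 58% of genes changed by 0.5 on the log2 scale, 80% at 1, 94% at 2 and 100% at 3, with 50 changed genes per size among 30142 and 3 unchanged genes called. The changed genes were drawn from all genes, including those below background and those with equal values across arrays, whose spread is small. These shares therefore do not give the power for genes above background. All sizes were planted in the same simulated set, where many passing genes ease the Benjamini-Hochberg threshold for the smaller changes. Abi1 alone passed in the real comparison, so the shares can also overstate what would be found there. In the real arrays Nfkbia, at a difference of 0.84 (SE 0.19), had a limma adjusted p of 0.786. In 100 simulated sets that kept the correlation of the arrays' residuals and held no change, camera with the preset correlation called a median of 10 lists and up to 18.

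Alternatives were quantile normalization, centring of each array on its median, leaving out dim genes, the mean of a gene's probesets, all probesets, a variance trend with robust moderation, no moderation, array weights, the replicate number as a block, other thresholds and each array left out in turn. Added after seeing the data were fits without KO replicate 1 and WT replicate 5, without WT replicates 2 and 3 and without KO replicates 1 and 2, the exact permutation of list scores, and lists without Abi1. That a list counts as turned when its mean changes sign, and not only when camera's direction does, was also settled after seeing the values. Figures were drawn with matplotlib 3.10.9.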

Results

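Gene expression was measured in LSK cells from the bone marrow of 9 mice. LSK cells lack the markers of mature blood lineages and carry Sca-1 and c-Kit, and they hold the haematopoietic stem cells and the earliest progenitors. The 4 knockout (KO) mice carried floxed Abi1 alleles and the Mx1-Cre transgene, and the 5 wild-type (WT) mice carried the floxed alleles without Cre. Both groups received 3 injections of poly(I:C), which turns on Mx1-Cre, at an age of 8 to 9 weeks, and the marrow came from mice of 12 to 14 weeks. Each array held amplified RNA of 1 mouse, from 5 ng of total RNA. Abi1 encodes an adaptor of the WAVE complex, which drives actin branching, and a partner of the ABL kinases. The comparison asked which transcripts differ in LSK cells once Abi1 is deleted. Only KO mice carried Cre, so an effect of Cre itself cannot be told apart from that of the deletion.

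The arrays measured 30142 named genes, of which 15652 to 16308 per array lay above the background level set by olfactory and vomeronasal receptor genes. Pairs of arrays correlated at 0.968 to 0.994 across genes, which are not independent replicates. KO replicate 1 and WT replicate 5 stood apart, with median correlations of 0.973 and 0.979 with the other arrays, against 0.987 to 0.992 for the other 7. KO replicate 1 also had the highest background level, 5.64 against 5.29 to 5.37, and the fewest genes above it. A control probeset marked pos exceeded one marked neg with a probability of 0.775 in KO replicate 1 and 0.756 in WT replicate 5, against 0.803 to 0.827. Kit, the receptor on which the cells were sorted, had a log2 signal of 14.38 ± 0.37 (SD, n = 4) in KO and 14.67 ± 0.16 (SD, n = 5) in WT. The difference of -0.30 did not pass the test (limma adjusted p = 0.786), and KO replicate 1 lay at 13.82, below the 14.53 to 14.58 of the other KO arrays. The myeloperoxidase gene Mpo, a granule gene of early myeloid cells, had mean signals of 16.76 in KO and 16.56 in WT. The other gate gene, Ly6a, had no probeset of its own in the annotation and was not analysed here.

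Abi1 fell by 5.73 on the log2 scale in the knockout, from 11.55 ± 0.064 (SD, n = 5) in WT to 5.82 ± 0.22 (SD, n = 4) in KO, on the probeset TC0200003098.mm.1. This is a 52.9-fold lower signal if the deposited values are log2, as their range implies. All 4 KO arrays lay between 5.59 and 6.11 and all 5 WT arrays between 11.49 and 11.65, so the labels match the targeted gene in every array. The standard error of the difference was 0.095 and limma's adjusted p was 7.42e-08. The exact two-sided permutation test gave p = 0.00794, the smallest that 4 arrays against 5 allow. The KO signal stayed above the background level of every KO array, at the percentile 97.7 of the receptor genes, so a weak signal remained.

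The differences of its relatives did not pass the test. Abi2, a paralogue of Abi1, had log2 signals of 10.64 ± 0.059 (SD, n = 4) in KO and 10.66 ± 0.14 (SD, n = 5) in WT. Its difference was -0.022, with an interval at the 95% level from -0.20 to 0.15, and 0.00028 with quantile normalization. Abi3 differed by 0.16, with an interval from -0.20 to 0.52. Among the other WAVE genes, Cyfip2 differed by -0.20, Nckap1l by -0.16, Wasf2 by -0.050, Brk1 by 0.17 and Nckap1 by 0.27. In KO replicate 1 Cyfip2 was 10.90, against 11.68 to 11.77 in the other KO arrays, and Nckap1l 11.69, against 12.87 to 13.01. Nckap1 was 5.68 in WT replicate 5, against 7.54 to 8.07 in the other WT arrays. The differences of Cyfip2, Nckap1l and Nckap1 thus each rest on a single array. Of the 10 WAVE genes measured, 1 fell past the threshold, Abi1 itself, over all genes tested and also adjusted over the list alone. The list was called as lower by camera (adjusted p = 0.0356, and adjusted p = 0.592 with an estimated correlation), but with Abi1 left out, chosen after seeing the data, its mean difference was 0.025 (adjusted p = 0.775). The call also ended without KO replicate 1, whose median correlation with the other arrays was 0.973 (adjusted p = 0.337), or WT replicate 1, 4 or 5 (adjusted p = 0.0520, 0.0839 and 0.0656).

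**Figure D1:**
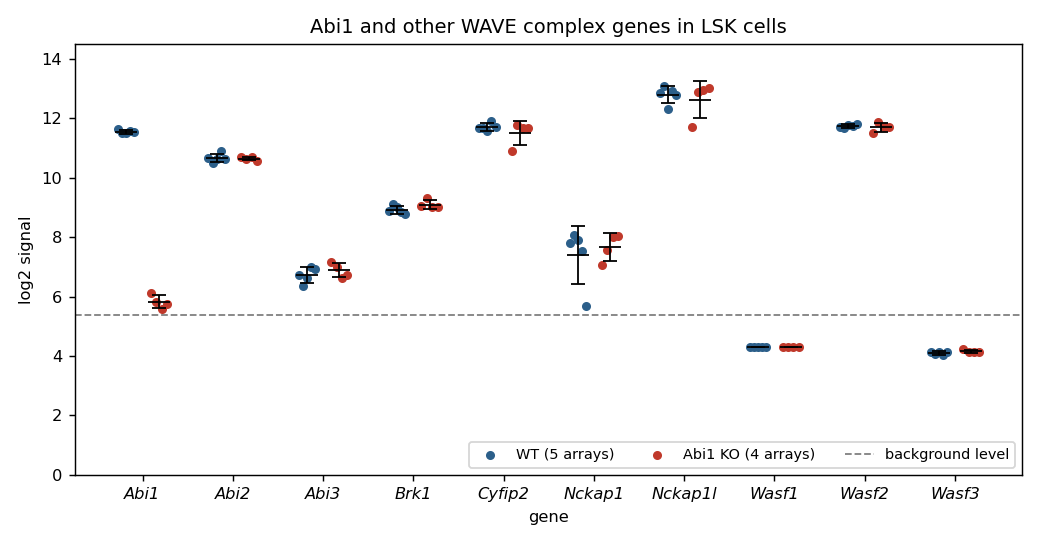
Log2 signal (vertical axis) of Abi1 and the 9 other measured WAVE complex genes (horizontal axis) in each array, WT in blue and KO in red, with black bars for the mean and SD over 5 WT or 4 KO arrays and a dashed line at the mean background level of 5.37. Abi1 lies at 5.59 to 6.11 in KO and 11.49 to 11.65 in WT, while the others overlap between the groups or lie below background.

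Abi1 was the 1 gene of 30142 that passed an adjusted p of 0.05 in limma, with 0 genes higher and 1 lower. At an unadjusted p under 0.05 there were 1509 genes, 1150 higher and 359 lower in KO, where 1507 are expected by chance, and 1005 without WT replicate 4. Of these genes 76.2% were higher in KO, and 60.8% when each array was centred on its median, with the median difference of all genes at 0.034 and -0.014. The groups did not overlap for 258 genes (0.856%), and chance gives 1.59% for 4 arrays against 5 where no values are equal. A value shared between the groups counts as overlap, and 25.8% of genes hold one value in at least 5 of the 9 arrays. Such ties lower the share found, so it cannot be set against 1.59%. The next smallest adjusted p belonged to Igll1, the surrogate light chain gene of early B cells, at 5.35 ± 0.15 (SD, n = 4) in KO and 4.68 ± 0.11 (SD, n = 5) in WT. Its limma adjusted p was 0.438, and both means lie below background.

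The genes that follow had the smallest unadjusted p per direction and did not pass, each with a limma adjusted p of 0.786. Among those with higher means in KO, the actin-severing protein gene Cfl1 differed by 0.34 (SE 0.066) and the mast cell protease gene Cma1 by 0.82 (SE 0.15). The ribosomal pseudogenes Rpl29-ps5 and Rpl7a-ps5 differed by 0.37 and 0.48, and the translation factor gene Eif3f by 0.23. The cytotoxic granule gene Nkg7 differed by 0.55, Mrgpra2a by 0.75, Fads3 by 0.50, Cox7a1 by 0.66, Rbm38 by 0.25 and Ang2 by 0.38. Among those with lower means, Adgrg7 differed by -0.35 (SE 0.072), the complement regulator gene Cd46 by -0.35 (SE 0.083) and Kbtbd7 by -0.32. Coq2 of ubiquinone synthesis differed by -0.28, Pard3b by -0.29, Trim68 by -0.34, Marf1 by -0.35, Zfp831 by -0.52, Sec61a2 by -0.21 and Mtx3 by -0.33. The immunoglobulin segment Ighv9-3 differed by -5.55 with a standard error of 1.51, since its WT arrays ran from 5.80 to 14.15.

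**Figure D2:**
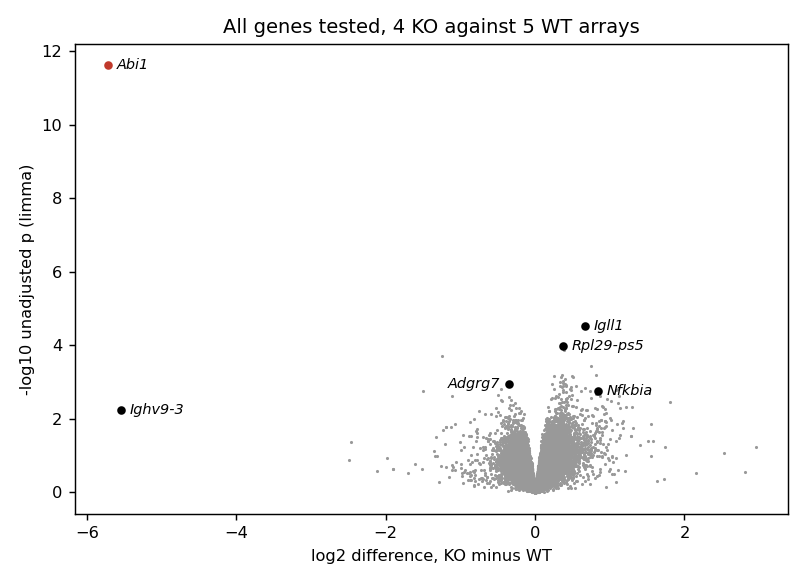
Log2 difference between the means of 4 KO and 5 WT arrays (horizontal axis) against -log10 of the unadjusted limma p (vertical axis), with a point for each of 30142 genes. Abi1, in red, at a difference of -5.73 is the gene past the adjusted threshold, and the 5 genes marked in black did not pass.

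Gene lists for blood lineages, signalling and actin regulation were compared next, and none of their calls stands under every test. With camera's preset correlation, 14 of 35 lists passed an adjusted p of 0.05, 8 with higher and 6 with lower values in KO, and 9 passed without WT replicate 5 (6 higher and 3 lower). The balance of directions rested on single arrays and dim genes: 12 higher and 2 lower without KO replicate 1, 5 and 8 without KO replicate 2, 10 and 4 without WT replicate 1, 8 and 2 without WT replicate 4, and 9 and 1 with dim genes left out. Quantile normalization ended 5 of these calls, those of the ABL and SRC, S phase, glycolysis, WAVE and plasma cell lists (adjusted p = 0.154, 0.151, 0.379, 0.0697 and 0.13). Leaving out dim genes ended the same 5 (adjusted p = 0.0563, 0.163, 0.187, 0.0563 and 0.216) and that of the B cell list, and centring each array on its median ended those of the S phase, glycolysis and plasma cell lists (adjusted p = 0.19, 0.143 and 0.145). Simulated arrays with the same correlation of residuals and no change gave a median of 10 called lists and up to 18. With the correlation estimated from the arrays 0 lists passed (smallest adjusted p = 0.442), and 2 had an unadjusted p under 0.05. An exact two-sided permutation of the array scores gave 0 lists (smallest adjusted p = 0.139), with 6 at an unadjusted p under 0.05. The rotation test fry called 1 list, the WAVE genes, with 5 at an unadjusted p under 0.05, and 2, the WAVE and B cell lists, when changes in either direction count. In the WAVE list Abi1 alone had an unadjusted p under 0.05 in limma. The smallest p of the B cell list belonged to Igll1, whose means lie below background. Fry was not run without these genes.

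Genes of granulocyte-monocyte progenitors had higher means in KO in 15 of 16 members, with a median difference of 0.47 (camera adjusted p = 0.000104, and adjusted p = 0.592 with an estimated correlation). No member passed over all genes, where 6 had an unadjusted p under 0.05 in limma, and 3 passed adjusted over the list alone: Nkg7, the Fc receptor gene Fcgr3 and the transcription factor gene Cebpe. Fcgr3 differed by 0.63, with WT replicate 3 at 8.04 and the other WT arrays at 7.39 to 7.56. The granule gene Ms4a3 differed by 1.01, the neutrophil elastase gene Elane by 0.85, the haptoglobin gene Hp by 0.90, and Csf3r, the G-CSF receptor gene, by -0.39. Array scores were 0.24 ± 0.26 (SD, n = 4) in KO and -0.20 ± 0.34 (SD, n = 5) in WT, with an exact permutation p of 0.0794.

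All 12 measured genes of mature neutrophils, 6 of them above background, had higher means in KO, with a median difference of 0.47 (camera adjusted p = 0.000195, and adjusted p = 0.592 with an estimated correlation). Adjusted over the list alone 0 members passed, and 2 had an unadjusted p under 0.05 in limma, the collagenase gene Mmp8 (0.27), which lies below background in both groups, and the chemokine receptor gene Cxcr2 (0.25). The calprotectin gene S100a8 had log2 signals of 12.58 and 10.87 in KO replicates 1 and 2, 6.52 and 7.48 in KO replicates 3 and 4, and 4.86 to 8.83 in WT. The mean difference of the list was 0.94, 1.81 with dim genes left out, and 0.62 without KO replicate 1, whose median correlation with the other arrays was 0.973. Without KO replicates 1 and 2, chosen after seeing the data, it was 0.11 (adjusted p = 0.281), and that of the progenitor list 0.34 (adjusted p = 0.00184).

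Targets of NF-kappaB, the transcription factor of inflammatory signalling, had higher means in KO in 24 of 26 members (median difference 0.30, camera adjusted p = 0.000195, and adjusted p = 0.592 with an estimated correlation). Nfkbia, which encodes the inhibitor that NF-kappaB itself induces, was 13.63 ± 0.16 (SD, n = 4) in KO and 12.79 ± 0.37 (SD, n = 5) in WT, and was the 1 member that passed adjusted over the list alone. The chemokine gene Cxcl2 differed by 1.56, Ier3 by 0.66 and Tnfaip3, a brake on the pathway, by 1.09. The array scores gave an exact permutation p of 0.0317 (adjusted p = 0.222 over the lists).

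Immediate early genes, which are switched on within minutes of a stimulus, had higher means in KO in 19 of 21 members (camera adjusted p = 0.000195, and adjusted p = 0.703 with an estimated correlation). Adjusted over the list alone 0 members passed, and 6 had an unadjusted p under 0.05 in limma. Klf2 differed by 1.58, Klf6 by 1.18, Ier2 by 0.93 and Jund by 0.62, while Fosb differed by 0.27 and Dusp1 by 0.069. The scores of WT replicates 2 and 3 were -0.89 and -1.08, those of the other WT arrays 0.088 to 0.37, and those of KO 0.16 to 0.67. The mean difference of the list was 0.56, and 0.36 without WT replicate 3. Without WT replicates 2 and 3, chosen after seeing the data, it was 0.073 (adjusted p = 0.930), and that of the NF-kappaB list 0.22 (adjusted p = 0.219).

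Inflammatory cytokines and their receptors had higher means in KO in 19 of 24 members (median difference 0.22, camera adjusted p = 0.00420, and adjusted p = 0.592 with an estimated correlation). Cxcl10, an interferon-induced chemokine gene, differed by 1.31, Ccl2 by 0.47, Il1b by 0.41 and the adaptor gene Myd88 by 0.41. These were the 4 members with an unadjusted p under 0.05 in limma, and 0 passed adjusted over the list alone. Scores were 0.14 ± 0.16 (SD, n = 4) in KO and -0.11 ± 0.069 (SD, n = 5) in WT, with an exact permutation p of 0.00794 (adjusted p = 0.139 over the lists). The call ended without KO replicate 2 (adjusted p = 0.178), without KO replicates 1 and 2 (adjusted p = 0.281) and without WT replicates 2 and 3 (adjusted p = 0.0527). Interferon response genes had higher means in 17 of 27 members and lower ones in 10 (camera adjusted p = 0.775), with Isg15 at 0.33 and Igtp at -0.26.

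B cell genes had higher means in KO in 11 of 14 members, with a median difference of 0.085, and 7 of the 14 lie above background (camera adjusted p = 0.00206, and adjusted p = 0.592 with an estimated correlation). Igll1, Ebf1 (difference 0.48), Vpreb3 (0.35) and Cd79b (0.46), genes of early B cells and their receptor, were the 4 members that passed adjusted over the list alone. The call ended without WT replicates 2 and 3 (adjusted p = 0.129) and with dim genes left out (adjusted p = 0.149).

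Mast cell, basophil and eosinophil genes had higher means in KO in 12 of 13 members (camera adjusted p = 0.00556, and adjusted p = 0.703 with an estimated correlation). The 3 that passed adjusted over the list alone were the IgE receptor gene Fcer1a (difference 1.21), the tryptase gene Tpsb2 (0.82) and Cma1, and the carboxypeptidase gene Cpa3 differed by 0.51. Megakaryocyte and platelet genes had higher means in 17 of 17 members (camera adjusted p = 0.0270, and adjusted p = 0.703 with an estimated correlation). The platelet chemokine genes Ppbp and Pf4 differed by 1.03 and 1.20, and Gp9 by 0.43. Ppbp was 9.00 in KO replicate 1, against 6.27 to 7.22 in the other KO arrays and 5.45 to 7.08 in WT. Adjusted over the list alone 0 megakaryocyte members passed, and 1 had an unadjusted p under 0.05 in limma. The mast cell call ended without KO replicate 2 (adjusted p = 0.0587) or 4 (adjusted p = 0.0584), and the megakaryocyte call without KO replicate 2, 3 or 4 (adjusted p = 0.0822, 0.106 and 0.0967). WT replicate 5 stood apart in these lineages. The signal of the erythroid carbonic anhydrase gene Car1 was 6.38 in this array and 15.40 to 16.99 in the other 8, and that of Pf4 was 10.42 and 14.33 to 15.83. Its scores were -1.22 for the megakaryocyte list and -1.09 for the mast cell list, and its control probesets marked neg had a median of 6.89, against at most 6.47 in the others. Without this array the mast cell list had a mean difference of 0.21 in place of 0.43 (adjusted p = 0.0693), and the megakaryocyte list 0.14 in place of 0.40 (adjusted p = 0.439). With KO replicate 1 left out too, chosen after seeing the data, both lists were called again, at 0.33 (camera adjusted p = 0.00154) and 0.10 (camera adjusted p = 0.0351). Erythroid genes had higher means in KO in 12 of 15 members and were not called (adjusted p = 0.723), with a WT score of -0.15 ± 1.19 (SD, n = 5). The erythroid score was -2.15 in WT replicate 5. It averaged 0.35 in the other 4 WT arrays, above the KO mean of 0.18. The higher KO mean of this list thus rests on WT replicate 5.

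**Figure D3:**
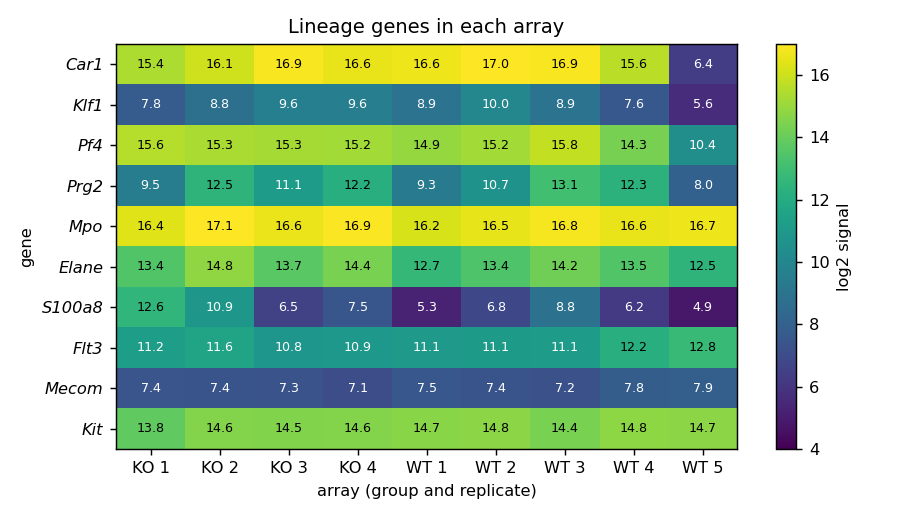
Log2 signal of 10 genes (vertical axis) in each of the 9 arrays (horizontal axis, group and replicate), printed in each cell and shown by colour. Car1 is 6.38 in WT replicate 5 and at least 15.40 elsewhere, and S100a8 is highest in KO replicates 1 and 2 at 12.58 and 10.87.

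Genes of mitosis had lower means in KO in 20 of 23 members, with a median difference of -0.30 (camera adjusted p = 1.04e-07, and adjusted p = 0.592 with an estimated correlation). The spindle checkpoint gene Bub1 differed by -0.53, the proliferation marker Mki67 by -0.50 and the motor protein gene Kif11 by -0.48. In KO replicate 1 Mki67 was 14.35, against 15.45 to 15.86 in the other KO arrays and 15.76 to 16.08 in WT. Bub1 (9.17) and Kif11 (11.45) were also lowest in that array. Adjusted over the list alone 0 members passed, and 1 had an unadjusted p under 0.05 in limma. Scores were -0.14 ± 0.19 (SD, n = 4) in KO and 0.11 ± 0.31 (SD, n = 5) in WT, with an exact permutation p of 0.262. WT replicates 2 and 3 had scores of 0.42 and 0.46. The mean difference was -0.25, -0.17 without KO replicate 1, -0.16 without WT replicate 3, and -0.025 without WT replicates 2 and 3 (camera adjusted p = 0.594).

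Genes of DNA replication and S phase had lower means in KO in 16 of 22 members (camera adjusted p = 0.0260, and adjusted p = 0.703 with an estimated correlation). Without KO replicate 1, whose median correlation with the other arrays was 0.973, their mean difference turned from -0.074 to 0.044 (adjusted p = 0.736), and the call ended without WT replicate 2, 3 or 4 (adjusted p = 0.282, 0.0892 and 0.0528). It was -0.020 without WT replicate 2, -0.047 without WT replicate 3, -0.15 without KO replicate 3 and -0.17 without WT replicate 5. Glycolysis genes had lower means in 12 of 17 members (camera adjusted p = 0.0270, and adjusted p = 0.703 with an estimated correlation). Without KO replicate 1 their mean difference turned from -0.067 to 0.026 (adjusted p = 0.736), and it was -0.11 without KO replicate 2, -0.12 without WT replicate 3 and -0.041 without WT replicate 4. The glycolysis call ended without WT replicate 1, 4 or 5 (adjusted p = 0.0543, 0.0839 and 0.138). Adjusted over the list alone 0 members of either list passed, and 0 had an unadjusted p under 0.05 in limma.

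ABL and SRC family kinases and their adaptors, partners of the Abi1 protein, had lower means in KO in 12 of 18 members and higher ones in 4, with a median of -0.044 (camera adjusted p = 0.00816, and adjusted p = 0.442 with an estimated correlation). Without KO replicate 1, whose median correlation with the other arrays was 0.973, their mean difference was -0.036 in place of -0.081 (adjusted p = 0.292). Plasma cell genes had lower means in 7 of 7 members (camera adjusted p = 0.0459, and adjusted p = 0.703 with an estimated correlation). The joining chain gene Jchain reached 13.83 in WT replicate 4, and without that array the mean difference of the plasma cell list turned from -0.20 to 0.037 (adjusted p = 0.907). The plasma cell call also ended without KO replicate 1, 2 or 3 (adjusted p = 0.237, 0.0757 and 0.151) or WT replicate 1 or 5 (adjusted p = 0.0530 and 0.0671), and the mean difference was -0.31 without KO replicate 4 and -0.32 without WT replicate 2. Adjusted over the list alone 0 members of either list passed, and 0 had an unadjusted p under 0.05 in limma.

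**Figure D4:**
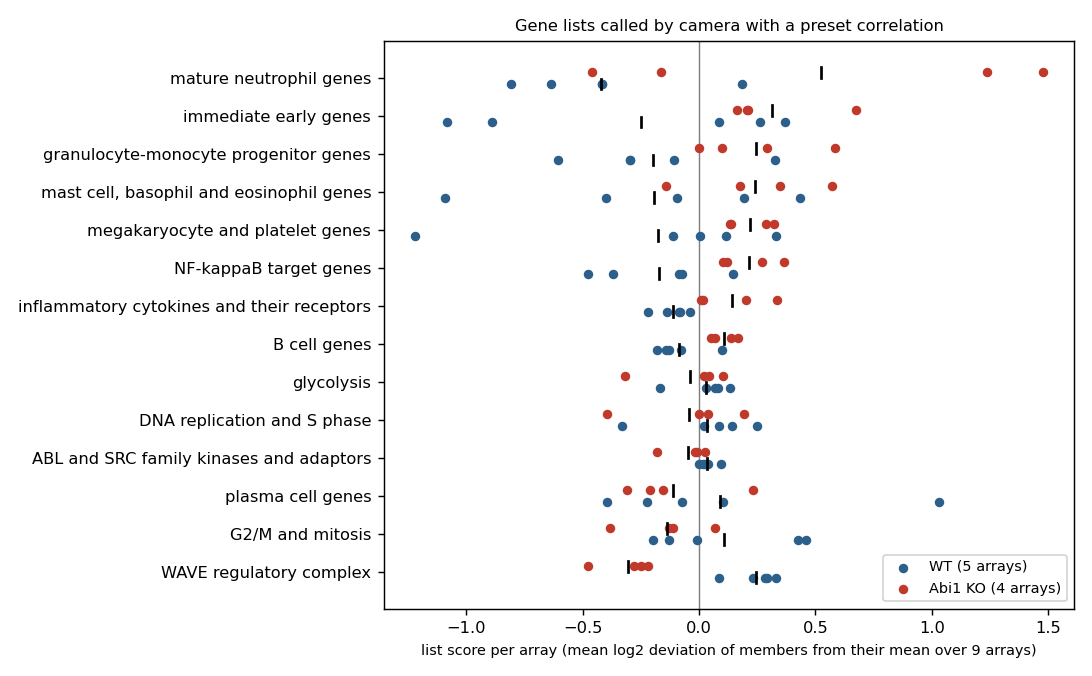
Score of each array (horizontal axis, mean log2 deviation of a list's members from their mean over 9 arrays) for the 14 lists called by camera with the preset correlation (vertical axis), WT in blue and KO in red, with black ticks for group means. KO and WT arrays overlap in all of them but the WAVE list and the inflammatory cytokine list, and KO replicates 1 and 2 hold the neutrophil scores of 1.48 and 1.24.

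The remaining 21 lists, the interferon and erythroid lists among them, were not called. Long-term stem cell genes had higher means in KO in 10 members and lower ones in 8 (camera adjusted p = 0.0559). Hlf, a transcription factor gene of stem cells, differed by -0.65, Robo4 by -0.48 and Slamf1 by 0.44. Slamf1 was 8.63 in WT replicate 5, against 10.21 to 11.04 in the other WT arrays and 9.61 to 11.28 in KO. The median of the stem cell list was 0.026 and its mean -0.049, so the signs differ, and camera pointed down. Lymphoid-primed progenitor genes had higher means in 7 of 12 members (adjusted p = 0.669), with the interleukin 7 receptor gene Il7r at 0.34. The Arp2/3 complex and other actin nucleators had higher means in 8 of 14 (adjusted p = 0.775), with Was at 0.35 and Arpc5 at 0.24, and integrins and adhesion receptors in 15 of 29 (adjusted p = 0.303). Mean and median of the integrins, lymphoid-primed genes, monocyte genes and small nucleolar RNAs were above 0, whereas camera, which compares with all other genes, pointed down.

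Among signalling and stress lists, JAK-STAT feedback and target genes had higher means in KO in 11 of 19 members (adjusted p = 0.795), with Cish at 0.57 and Myc at 0.20, and p53 targets in 12 of 19 (adjusted p = 0.775), with Bbc3 at 0.25. BCL2 family and caspase genes had higher means in 9 of 16 (adjusted p = 0.723), with Pmaip1 at 0.31 and Bid at 0.24. For the unfolded protein and integrated stress response it was 11 of 17 (adjusted p = 0.536), with Atf4 at 0.31 and Dnajb9 at 0.39, and for heat shock proteins 7 of 9 (adjusted p = 0.284), with Bag3 at 0.17. Myelofibrosis mediators and matrix genes had higher means in 18 of 23 (adjusted p = 0.132), with Tgfb1 at 0.32. Antigen presentation genes had lower means in 10 of 13 (adjusted p = 0.0641), although B2m differed by 0.30. Oxidative phosphorylation genes had higher means in 16 of 23 (adjusted p = 0.212), with Cox6b1 at 0.46 and Cox5a at 0.41, and cytoplasmic ribosomal proteins in 10 of 14 (adjusted p = 0.227), with Rpl10a at 0.27.

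Other markers of cells that a sort can carry were not called either. Monocyte and macrophage genes had higher means in KO in 8 of 15 members (adjusted p = 0.454), although Ly6c2 differed by 1.51 (SE 0.62). Dendritic cell genes had higher means in 8 of 13 (adjusted p = 0.775), with Cd209a at 0.40, and T cell genes in 8 of 13 (adjusted p = 0.303). NK cell and cytotoxic lymphocyte genes had higher means in 11 of 13 (adjusted p = 0.141), with Nkg7 the 1 member past the threshold adjusted over the list alone. Stromal and endothelial genes had higher means in 14 of 18 (adjusted p = 0.262), with 5 members above background. Small nucleolar RNAs had higher means in 35 of 62 and lower ones in 27 (adjusted p = 0.682), with Snord49b at 1.81, Snord42a at 1.08, Snord35a at -1.51 and Snord85 at -0.45.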

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

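The tests of NF-kappaB, progenitor and erythroid genes were chosen after the result was seen, whereas the counts over splits of the arrays were planned before. Among 126 groups of gene values and 70 groups of list scores, 5 and 2 held an array far from the others of its group, and chance gives about 1 group in 20.

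Of 100 splits of the 9 arrays into 4 and 5, the real one included, 2 gave at least 1 gene, and the highest of the others was 1. Every other split mixes KO and WT arrays, which puts the gap of Abi1 into the spread within groups. The count is also of any gene, so it does not test the call of Abi1. At an unadjusted p under 0.05 the real split gave 1509 genes and the others a median of 828, with 2683 at most. Of the 100 splits 21, the real one included, gave as many as the real one, so the arrays hold structure other than genotype. Chance is not excluded for the 14 called lists, since 14 of 100 splits gave as many, with 18 the highest of the others.

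A probeset outside the gene tests was lower in KO. The unnamed probeset TC0200003102.mm.1, whose number follows shortly on that of Abi1, was at 5.24 ± 0.44 (SD, n = 4) in KO and 9.62 ± 0.68 (SD, n = 5) in WT, a difference of -4.38 (limma adjusted p = 0.0210 among 35352 probesets not named by 1 gene). It was the 1 of these that passed, with 1773 at an unadjusted p under 0.05. Of the probesets numbered between them, chosen after seeing the data, TC0200003101.mm.1 differed by -2.72 and TC0200003099.mm.1 by -1.93, which did not pass (adjusted p = 0.114 and 0.772), and TC0200003100.mm.1 by 0.30.

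Several named genes and a list had 1 array far from its group. Kit was 13.82 in KO replicate 1, against 14.53 to 14.58 in the other KO arrays, and 14.39 in WT replicate 3, against 14.70 to 14.78. Igll1 was 4.49 in WT replicate 5, against 4.71 to 4.74. Fcgr3 was 8.04 in WT replicate 3, against 7.39 to 7.56. Mtx3 was 6.27 in KO replicate 1, against 6.32 in each of the others. The immediate early gene score of KO replicate 2 was 0.67, against 0.16 to 0.21.

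The megakaryocyte score of WT replicate 5 was -1.22, against -0.11 to 0.33 in the other WT arrays, and its erythroid score was -2.15, against a mean of 0.35 ± 0.45 (SD, n = 4). Weak hybridisation of the array is argued against by its spike-ins, of which 4 of 4 lay inside the range of the other arrays. A loss of signal for all progenitor genes is argued against by the lymphoid-primed and stem cell scores. These differed from the other WT arrays by 0.34 and -0.13. The granulocyte-monocyte score differed by -0.12, against an SD of 0.39 over those arrays, and averages members that went opposite ways. In WT replicate 5 Elane (12.47) and Cebpe (4.98) were lower than in every other array, and Csf3r (11.80) was higher. Stem cell genes also split, with Hlf (11.62) and Meis1 (13.52) above every other array and Slamf1 (8.63) and Vwf (5.83) below. A lower share of all committed progenitors therefore stays open. Other signs of array or RNA quality did stand apart in this array, with the lowest probability that a pos control exceeds a neg one, 0.756 against 0.775 to 0.827, the highest median of neg controls, 6.89 against at most 6.47 elsewhere, and a median correlation with the others of 0.979, above KO replicate 1 only. Poorer RNA or labelling, a sort with few cells of the erythroid, megakaryocyte and mast cell branch, or a difference of that mouse, which the labels set apart in nothing, may account for the values, and none of these was tested.

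The higher NF-kappaB score in KO moves with immediate early genes: with their score in the model and shared genes left out, the difference went from 0.38 (SE 0.14) to 0.19 (SE 0.061), a ratio of 0.493, and to ratios of 0.340 without WT replicate 4 and 0.614 without WT replicate 3. That lies just under the bound of 0.5 set for such a source, so variation of immediate early genes between arrays could account for part of the difference, and the 0.19 that remained lay over 2 standard errors from 0. With the mature neutrophil score in the model, the difference was 0.39 (SE 0.19), from 0.39 (SE 0.14). That is a ratio of 0.999, past the bound of 0.75 at over 2 standard errors. The ratio was 0.726 without WT replicate 3, under that bound, and 1.18 without KO replicate 3. The slope on the neutrophil score was 0.00047 (SE 0.12), and that score differed by 0.94 between the groups. With a slope this uncertain, the test cannot decide whether mature neutrophils contribute. A rule that each bound also hold without any single array was tried after the values were seen and is not used. Under it neither of these tests, nor the next one on progenitors, would meet its bound. An effect of the knockout, or of the Cre that only KO mice carry, on NF-kappaB signalling, with or without the immediate early genes, stays open.

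The higher granulocyte-monocyte progenitor score in KO stood beside higher mature neutrophil genes, of cells that lineage depletion should remove, with a slope of 0.24 (SE 0.15) on the neutrophil score, less than 2 standard errors from 0. With the neutrophil score in the model the difference went from 0.44 (SE 0.21) to 0.22 (SE 0.24), a ratio of 0.494, just under the bound of 0.5. Leaving out an array gave ratios of 0.159 without KO replicate 4 to 0.732 without WT replicate 3, so neutrophils in the sort could account for part of it. Without KO replicates 1 and 2 the neutrophil list differed by 0.11 (adjusted p = 0.281) and the progenitor list by 0.34, but the progenitor scores of the KO arrays left, 0.00083 and 0.29, lie inside the WT range of -0.61 to 0.32, so this excludes nothing. S100a8, among the most abundant neutrophil transcripts, was at 12.58 and 10.87 in KO replicates 1 and 2 and at most 8.83 in the other arrays, and more granulocytic progenitors in KO stay open beside neutrophils.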

How the results depend on the processing

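The fits without 2 arrays, the exact permutation of list scores and the lists without Abi1 were chosen after seeing the data. Abi1 kept its direction and its call in all 19 alternatives, with differences of -5.84 to -5.65 and adjusted p from 9.11e-10 to 0.00148. The count of 1 gene became 2 with all probesets (TC0200003102.mm.1 was added), 2 with array weights (Igll1 was added, adjusted p = 0.0157), and 169 at an unadjusted p of 0.05 with a 1.5-fold change, which drops the adjustment. Leaving out each array in turn gave 1 gene each time. The count of 1509 of 30142 at an unadjusted p under 0.05 became 910 of 15071 without dim genes and 3366 of 65956 with all probesets, and 1005 (without WT replicate 4) to 1924 (without WT replicate 3) leaving out each array.

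The number of called lists, 14, was 9 with quantile normalization, 9 without WT replicates 2 and 3, 0 with an estimated correlation, 1 with fry, 0 by exact permutation, and 9 (without WT replicate 5) to 15 leaving out each array. These were not always among the 14: 7 of the 9 without WT replicates 2 and 3 and 9 of the 14 without KO replicate 1 were, in the same direction. Without KO replicate 1 and WT replicate 5 the ABL and SRC, S phase, WAVE and plasma cell calls ended (adjusted p = 0.267, 0.182, 0.512 and 0.264). The mast cell and megakaryocyte calls, which ended without WT replicate 5 alone, held in that fit. Median centring moved the means of the ABL and SRC, S phase and glycolysis lists to -0.13, -0.12 and -0.11. Over all alternatives the 14 lists kept their call in 202 cases, lost it in 97 and turned in 9. The S phase list had mean differences of -0.165 to 0.044 leaving out each array (turned without KO replicate 1), 0.034 without WT replicates 2 and 3 and 0.082 without KO replicates 1 and 2. Glycolysis had -0.117 to 0.026 (turned without KO replicate 1), 0.039 without KO replicate 1 and WT replicate 5 and 0.0025 without KO replicates 1 and 2. Plasma cell genes had -0.32 to 0.037 (turned without WT replicate 4). The immediate early list had 0.073 without WT replicates 2 and 3, where camera pointed down, and the WAVE list 0.025 without Abi1. Abi2 had 0.00028 with quantile normalization and -0.065 to 0.035 leaving out each array (turned without KO replicate 4, at 0.0047, and WT replicate 4), and Abi3 -0.0042 without WT replicates 2 and 3. Except where stated, the cause was not tested.

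The share of genes at an unadjusted p under 0.05 that were higher in KO was 76.2%, 74.1% with quantile normalization, 60.8% with median centring and 59.9% without KO replicate 1 and WT replicate 5. With the replicate number as a block, 1 gene and 10 lists passed (Abi1 difference -5.73, adjusted p = 0.00148). WT replicate 5 has no KO array of its number and adds nothing to the differences in that fit, so the block also leaves this array out. The mast cell, megakaryocyte, glycolysis and WAVE calls ended with the block (camera adjusted p = 0.146, 0.448, 0.222 and 0.165). Same-numbered arrays did not all deviate together (correlations -0.178, 0.146, -0.0135 and 0.270), so the numbers were not read as pairs. Signal over background limits the rest, since 16023 of 30142 genes have means above it.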

Other observations

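The genes of these observations were chosen after their values were seen, and none was tested as a group difference unless a p is given. WT replicate 5 had low levels of erythroid, megakaryocyte and eosinophil genes that the other 8 arrays express. The erythroid transcription factor gene Klf1 was 5.63 in this array, against 7.60 to 10.04 elsewhere, and the blood group genes Kel, Ermap and Rhag were 5.79, 5.51 and 5.27, against at least 7.54, 8.74 and 7.60. Platelet genes Gp5, Treml1 and Pf4 were 6.38, 7.47 and 10.42, against at least 8.62, 10.32 and 14.33, and the eosinophil granule gene Prg2 was 8.04, against 9.32 to 13.07. Flt3, which marks lymphoid-primed progenitors, was 12.78 in the same array, against 10.81 to 12.15 in the others. Immunoglobulin genes left out, 48 genes lay more than 2 log2 units below the median of the other arrays in WT replicate 5 and 33 in KO replicate 1, beside 1 to 5 in the other 7.

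Immunoglobulin V genes varied widely between mice. Of 199, 62 were higher in KO (median -0.245), and 45 without KO replicate 1 (median -0.279). Their mean score was 1.30 in WT replicate 4 and -0.72 in WT replicate 2, and the KO arrays ran from -0.69 to 0.35 (exact permutation p = 0.476). Jchain, the joining chain gene of secreted immunoglobulin, ran from 9.40 in KO replicate 2 to 13.83 in WT replicate 4. Gdpd3 lay at a high level of 13.43 to 14.81 in 5 arrays (KO replicates 1, 2 and 3, WT replicates 4 and 5) and at 6.18 to 6.53 in the other 4, with nothing between. Ifi44l, an interferon-induced gene, was 8.91 and 8.83 in WT replicates 3 and 5 and 4.60 to 4.99 in the other 7 arrays.

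Means in KO were higher in 3 classes of short or processed RNA, picked because they looked high, and their scores were highest in KO replicate 1. The small nucleolar RNAs, a list fixed before the data were examined, were higher in 35 of 62 only (median 0.070, camera adjusted p = 0.682, direction down). Ribosomal protein pseudogenes, which share sequence with their parent genes on the array, were higher in 201 of 206 (median 0.23, exact permutation p = 0.0397), and without KO replicate 1 in 194 (median 0.14). The Rnu small nuclear RNA genes were higher in 14 of 14 (median 0.57, exact permutation p = 0.0238), and 5S ribosomal RNA genes in 65 of 69 (median 0.28, exact permutation p = 0.00794, the smallest possible). Without KO replicate 1, 13 and 59 of these were higher, with medians of 0.32 and 0.20. Because of how the classes were picked, these p values are too small. The control probesets marked pos had a median of 10.64 in KO replicate 1 and 10.72 in WT replicate 5, against 10.98 to 11.28 in the others.

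The differences of genes beside Abi1 on its chromosome did not pass, with Apbb1ip at -0.068, Acbd5 at -0.034, Mastl at -0.18 and Yme1l1 at -0.22 (limma adjusted p of 0.786 to 0.920).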
